A study of Bos taurus with 15 samples.

How the data were processed

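Bovine (Bos taurus) oocytes were profiled by RNA sequencing in 15 libraries, 3 in each of 5 groups: fresh, helium 5.6 M, helium 6.6 M, nitrogen 5.6 M and nitrogen 6.6 M, where M gives the concentration of the cryoprotective agent. Groups and replicate numbers were taken from the sample labels, and the helium 5.6 M libraries carry the numbers 3, 4 and 5 there. Per the labels' protocols, RNA came from single cells, cDNA was made with SMARTer kits, libraries were built with SMART-Seq and Ovation kits, and cumulus cells were removed with hyaluronidase after maturation. Whether a library held 1 oocyte or several, and whether counting used the strand, is not stated in the labels. Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.3.0 and the genome build UMD3.1 were used, with no role or order given. Read filters and the handling of reads that map to several places are not given in the sources used here. No batch, sequencing date or lane was given either.

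The deposited table held 24616 Ensembl genes, of which 6062 had no gene symbol and 37 lay on the mitochondrial genome. Counts were deposited as whole numbers per gene and library with no scaling, per the file headers and the values. FPKM values were deposited beside them, as counted fragments scaled by gene length and by the library's total, per the file headers. In all 180473 values with a count above 0, the FPKM value equalled the count divided by gene length and library total within 0.1 percent, so both columns hold the same measurement. Any count at all was present for 16294 genes. Library totals ranged from 1601519 to 8569618 counts. Gene spans are those of the table on UMD3.1, and no genome sequence was used.

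Tests were run in R 4.3.3. The design written before the data were examined foresaw limma on FPKM values unless the table held raw counts, in which case edgeR would be used, and edgeR was used because it held counts. The gene lists, the rule for naming genes and most alternatives were chosen before the data were examined as well. Genes passed edgeR's filterByExpr for the 5 groups, which left 8441 genes. Libraries were scaled by the trimmed mean of M-values (TMM), and 1 robust quasi-likelihood fit of all 5 groups was made with edgeR 4.0.16, without a replicate block. Each comparison was a contrast of this fit with Benjamini-Hochberg adjustment over the 8441 genes and a threshold of 0.05. Comparisons were each vitrified group against fresh, all vitrified groups against fresh, helium against nitrogen, high against low concentration, their interaction, and the coolants and concentrations within each level of the other factor. Standard errors of log2 fold changes came from the same fit. CPM values per gene are TMM-scaled, with the SD between libraries, except for markers of other cell types, given as plain CPM.

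Named genes followed a rule set before the data were examined: genes with a symbol, past the threshold, with a mean of at least 5 FPKM in the higher group, and with no overlap between the libraries of both groups (for comparisons that pool groups, the same sign in each single-group difference instead). The 12 largest rises and 12 largest falls were taken, and where fewer than 10 genes met this, those with the smallest p filled the number to 10 and were given as values that did not pass. Not every gene that met the rule is reported here. The 21 gene lists held 960 symbols, of which 794 matched the table, and a list needed at least 5 tested genes. They covered oocyte-specific and maternal-effect genes, the meiotic cell cycle, the spindle and cytoskeleton, mitochondrially encoded genes, nuclear oxidative phosphorylation, antioxidant defence, heat shock proteins, the unfolded protein response, apoptosis regulators, calcium handling and egg activation, osmotic transport, lipid metabolism, carbohydrate metabolism, maternal mRNA storage and decay, DNA methylation and histone modification, DNA repair, autophagy and the proteasome, cytosolic ribosomal proteins, immediate early genes, cumulus and granulosa markers, and blood and immune markers. Lists were tested against all other genes with camera of limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. Adjustment was over the 21 lists of a comparison. Gene families with a shared symbol stem and at least 10 tested members, 74 in all, were tested in the same way after the data had been seen.

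Shares of counts on mitochondrial genes and numbers of genes at 1 FPKM or more were compared with exact permutation tests, two-sided. Intervals of single shares are 95% exact Clopper-Pearson intervals. Same-group libraries differed by 5.52 to 30 in chi-square per degree of freedom, so none was a copy of another. Deviations from the group means correlated over 0.1 in all 3 same-number pairs of helium 6.6 M and fresh (0.147, 0.306 and 0.227). No other comparison with 3 pairs did so. The replicate number was therefore taken to pair those libraries, which is a hint from the same data only. Helium 6.6 M library 3 correlated more with fresh library 1 (0.294) than with fresh library 3. The labels do not say what the numbers mark. Shared controls were handled with 20 simulations of unchanged groups against shared fresh libraries, which were simulated as well.

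The procedure was tested on simulated data: counts were drawn from the means and totals of these libraries, with 200 of 8441 genes changed. For helium 5.6 M against fresh it recovered 4.48% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 87.9% of those changed 4-fold, with 0 wrong calls. For all vitrified against fresh it recovered 23.9%, 59.7% and 90.9% at the same folds with 2 wrong calls, and for helium against nitrogen 23.9%, 80.6% and 98.5% with 8 wrong calls. Every group was given the same spread per gene and no batch was simulated. The recovery and the wrong calls may therefore differ in the real libraries. A shift of 0.3 on the log2 scale in the nuclear oxidative phosphorylation list, simulated for all vitrified against fresh, gave an adjusted p of 9.4e-09 by camera with 0 other lists called. Genes were drawn independently of each other, so the 0 says nothing about false list calls where genes vary together. Regroupings of the real libraries gave a median of 2 lists and at most 7 for that comparison.

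Alternatives planned before the data were examined were no count filter, a mean of at least 5 FPKM, median-ratio scaling, DESeq2 1.42.0 with its size factors, limma on log2 FPKM with a pseudocount of 0.1, quantile normalization, only the libraries compared, the replicate number as a block, an estimated correlation for lists, other FPKM minimums for detection, other ways to express the mitochondrial share, and leaving out each library in turn. Added after the data had been seen were limma on log2 FPKM with a pseudocount of 1 (10055 genes at 1 FPKM or more in 3 libraries), counts thinned to the smallest total, removal of a gene length trend, depth class (7 deeper against 8 shallower libraries) as a term, fits of the deeper or shallower libraries alone, and for helium 6.6 M against fresh the replicate block joined with thinned counts, the length trend, depth class or only the libraries compared. A check of GC content was not run, since no genome sequence of this build was used here.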

Results

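RNA sequencing measured transcript abundance in bovine oocytes that were either left fresh or vitrified, which means cooled so fast in a concentrated cryoprotectant that the water turns to glass without ice. The 15 libraries formed 5 groups of 3: fresh oocytes, oocytes plunged into liquid helium with 5.6 or 6.6 M cryoprotective agent, and oocytes plunged into liquid nitrogen at the same concentrations. The series asked how the temperature of the coolant and the concentration of the cryoprotectant affect the oocyte's mRNA. The series title calls the oocytes immature, whereas the sample labels describe oocytes matured in vitro for 22 to 24 h at 38.5 °C, so the stage is left open here. Total counts per library ranged from 1601519 to 8569618. Helium libraries were the deepest, with 6346848 to 8569618 counts at 5.6 M and 6906940 to 7330690 at 6.6 M. Fresh libraries held 1601519 to 2822837 counts and nitrogen 5.6 M libraries 1790900 to 2333545. In the nitrogen 6.6 M group, library 3 held 7392972 counts and libraries 1 and 2 held 1987931 and 2613014. Depth therefore went almost entirely with the coolant. The 7 deeper libraries were the 6 helium libraries and nitrogen 6.6 M library 3, and the 8 shallower ones were the rest. Nothing in the labels says whether the replicates came from separate animals or cultures, so every p-value measures only the spread between these libraries, which may be technical.

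Mitochondrial transcripts and the number of genes detected were compared first, as measures of RNA content that vitrification could alter. Genes of the mitochondrial genome, which encodes core subunits of the respiratory chain, took 5.97% ± 2.38 (SD, n = 3) of all counts in fresh oocytes and 4.12% ± 1.04 (n = 12) after vitrification. The shares were 3.75% ± 0.260 with helium at 5.6 M and 3.59% ± 0.727 at 6.6 M (n = 3 each). They were 5.17% ± 1.11 with nitrogen at 5.6 M and 3.96% ± 1.36 with nitrogen at 6.6 M (n = 3 each). The highest single share was 8.66% in fresh library 1 (95% exact Clopper-Pearson interval 8.62 to 8.70) and the lowest 2.41% in nitrogen 6.6 M library 3 (2.40 to 2.42). These intervals cover counting error only. The difference of -1.86 percentage points between vitrified and fresh libraries did not pass an exact permutation test, two-sided, over 455 splits (p = 0.0527). It was -0.513 without fresh library 1 (p = 0.462), and -2.77 without fresh library 2 (p = 0.033), by the same exact test. It was -1.95 without nitrogen 5.6 M library 1 (p = 0.0412) and -2.05 without nitrogen 5.6 M library 2 (p = 0.0275), by the same exact test. The difference between helium and nitrogen libraries was -0.899 points (n = 6 and 6, exact permutation test, two-sided, p = 0.149). Among the 8 shallower libraries the 5 nitrogen ones held 5.00% ± 0.830 and the 3 fresh ones 5.97% ± 2.38 (exact permutation test, two-sided, p = 0.5). Among the 7 deeper libraries the 6 helium ones held 3.67% ± 0.496 and the 1 nitrogen library 2.41% (exact permutation test, two-sided, p = 0.143, the smallest that 7 splits allow). Detected genes, at 1 FPKM or more (fragments scaled by gene length and library total), numbered 9042 ± 292 per vitrified library (n = 12) and 8906 ± 728 per fresh library (n = 3). The difference of 136 was smaller than the spread of either group (exact permutation test, two-sided, p = 0.6). That difference was -40.3 without fresh library 1, 554 without fresh library 2 (p = 0.044, same exact test) and -106 without fresh library 3.

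**Figure D1:**
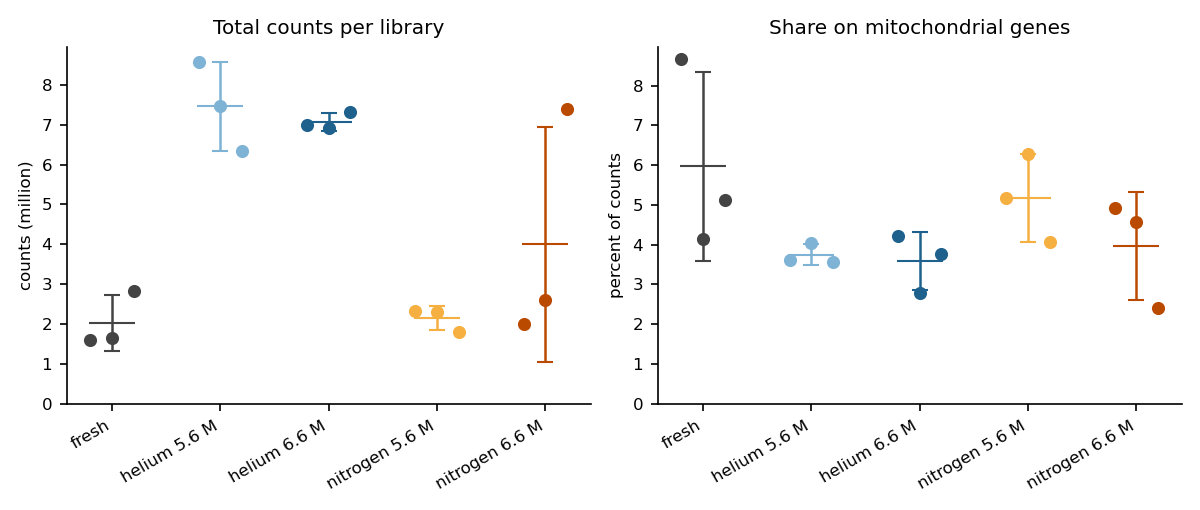
Total counts (left) and percent of counts on mitochondrial genes (right) of each library by group, with points for libraries, horizontal lines for group means and bars for 1 SD (n = 3). Helium libraries and nitrogen 6.6 M library 3 held 6346848 to 8569618 counts and the other libraries 1601519 to 2822837.

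All 12 vitrified libraries were set against the 3 fresh ones to ask which transcripts differed after vitrification, whatever the coolant or concentration. SNRPC, which encodes a protein of the U1 small nuclear ribonucleoprotein that recognises introns at their start, rose 3.83-fold after vitrification. It stood at 79.5 ± 18.8 CPM (counts scaled to a common library total; SD, n = 3) in fresh oocytes and at 307 ± 45.3 (n = 12) in vitrified ones. Transcripts of the cationic amino acid transporter SLC7A3 rose from 309 ± 70.0 to 691 ± 98.3 CPM. Those of UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose from 334 ± 103 to 705 ± 86.1 and those of the peroxide-reducing enzyme PRDX2 from 208 ± 35.1 to 416 ± 64.1. Transcripts that fell included the RNA-binding protein gene FUBP3, from 68.2 ± 4.28 to 38.4 ± 6.88 CPM, and the signalling adaptor gene TIFA, from 158 ± 59.8 to 82.8 ± 17.1. TMED7, a cargo receptor gene of the early secretory pathway, fell from 245 ± 25.5 to 163 ± 12.8. In each of these 7 genes all 12 vitrified libraries lay beyond all 3 fresh ones. SNRPC (ENSBTAG00000024549) spans 8726525 to 8737237 on chromosome 23 of UMD3.1 and SLC7A3 85010185 to 85015644 on chromosome X. PRDX2 spans 13845843 to 13848479 on chromosome 7 and FUBP3 100903350 to 100952801 on chromosome 11.

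By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 43 of 8441 genes passed between vitrified and fresh oocytes, 23 higher and 20 lower. The log2 fold change of SNRPC was 1.94 (SE 0.18, adjusted p = 1.46e-05) and that of SLC7A3 1.15 (SE 0.18, adjusted p = 0.00823) by edgeR. That of PRDX2 was 0.99 (SE 0.15, adjusted p = 0.00717) and that of UBE2C 1.08 (SE 0.19, adjusted p = 0.0179) by edgeR. Further genes rose by 0.89 to 1.03 on the log2 scale, with 12 of 12 vitrified libraries above every fresh one. They were ISCU, the scaffold of iron-sulfur cluster assembly, the spliceosome gene CWC15, WDR13 and the mitochondrial ribosomal protein gene MRPL20. The ribonuclease P gene POP4, the circadian repressor gene CIART and the germ-cell lactate dehydrogenase gene LDHC were the others. SEC61G, a subunit of the protein translocation channel, rose by 0.89 (SE 0.19, edgeR adjusted p = 0.0386) with 11 of 12 libraries above the fresh ones. Among genes that fell by edgeR, the log2 fold change was -0.84 for FUBP3 (SE 0.16, adjusted p = 0.0179), -0.94 for TIFA (SE 0.18, adjusted p = 0.0196) and -0.59 for TMED7 (SE 0.12, adjusted p = 0.0228). ND3, a complex I subunit encoded in the mitochondrion, fell by 1.38 (SE 0.24, edgeR adjusted p = 0.0179), with 7 of 12 below all fresh ones. PTMS, SHKBP1, LANCL1 and the guidance receptor gene ROBO1 also fell, with log2 fold changes of -1.28, -1.12, -0.79 and -0.64. Metazoa_SRP, RPL37A and HIST2H2BE passed as lower too, at -1.97, -1.06 and -1.04. These genes and the mitochondrial ones have near-identical copies between which the counting could have divided reads, so their values are uncertain. Of the 43 genes, 7 lay on the mitochondrial genome and all 7 were lower. The count fell to 5 without fresh library 1, 26 without helium 5.6 M library 3, and 26 without helium 6.6 M library 3. It was 28 without nitrogen 5.6 M library 1 and 243 without fresh library 2. With depth class as a term, which rests on nitrogen 6.6 M library 3, 1 gene passed. The 43 genes kept a median of 0.942 of their log2 fold change (quartiles 0.698 to 1.04) and 43 of 43 their sign. They were called in these same libraries, so the kept shares and signs add little support.

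**Figure D2:**
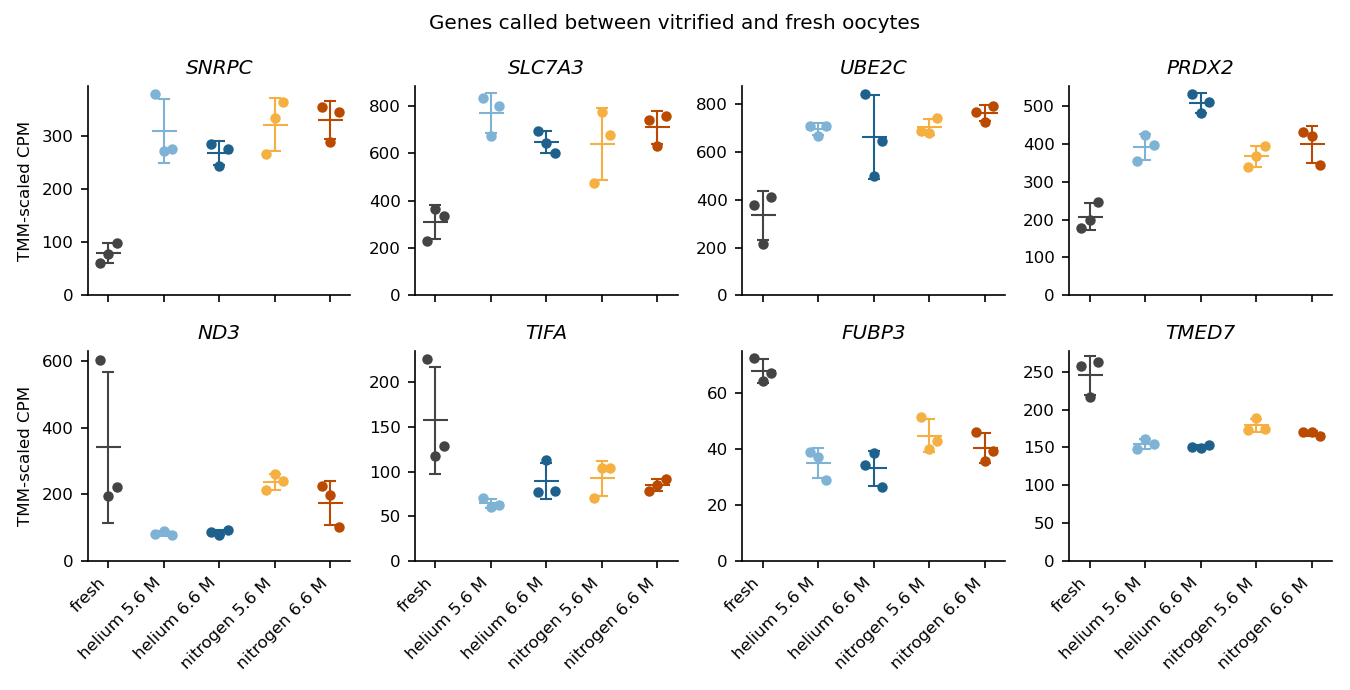
CPM (scaled by the trimmed mean of M-values) of 8 genes in every library by group, with points for libraries, horizontal lines for means and bars for 1 SD (n = 3). SNRPC, SLC7A3, UBE2C and PRDX2 lay higher in the vitrified groups and ND3, TIFA, FUBP3 and TMED7 lower.

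Among the 21 gene lists fixed before the data were examined, for all vitrified vs fresh, the 12 mitochondrially encoded protein genes were lower in vitrified oocytes. Their median log2 fold change was -0.77, with 12 of 12 below 0 (camera adjusted p = 3.2e-08, but adjusted p = 0.307 with an estimated correlation). Fresh library 1 carried much of this difference, and without it the list did not pass (camera adjusted p = 0.111). Summed over the list, fresh libraries 1, 2 and 3 held 69190, 26170 and 41230 CPM (not scaled), and helium libraries 20030 to 32140. Of these genes ND3 fell over all genes tested and 9 fell adjusted over the list alone, including ND6 (-1.09) and ND2 (-0.89). Nuclear genes of oxidative phosphorylation were higher as a list, with 34 of 41 above 0 at a median of 0.19 (camera adjusted p = 0.000569, adjusted p = 0.307 with an estimated correlation). None of these 41 passed over all genes and 2 passed adjusted over the list alone, the complex I subunit genes NDUFA10 and NDUFS3 (log2 fold changes 1.69 and 0.98). Meiotic cell cycle genes were higher at a median of 0.11 with 27 of 39 above 0 (camera adjusted p = 0.0277, adjusted p = 0.151 with an estimated correlation). The spindle checkpoint gene BUB3 rose by 0.75 and the cyclin gene CCNB2 by 0.64 over all genes, and 4 meiotic genes rose adjusted over the list alone, with SPC25 and AURKB added. Oocyte-specific and maternal-effect genes were higher at a median of 0.15 (19 of 28 above 0, camera adjusted p = 0.0104, adjusted p = 0.449 with an estimated correlation). The ubiquitin hydrolase gene UCHL1 rose by 0.66 over all genes and adjusted over the list alone. Antioxidant genes were higher at a median of 0.06 (17 of 25 above 0, camera adjusted p = 0.0215, adjusted p = 0.151 with an estimated correlation). PRDX2 was the 1 member that rose over all genes and adjusted over the list alone. Genes of glycolysis, the pentose phosphate pathway and the citrate cycle were higher at a median of 0.16 (18 of 27 above 0, camera adjusted p = 0.0288, adjusted p = 0.433 with an estimated correlation). None of their members passed by edgeR over all genes, and 0 passed adjusted over the list alone.

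The other 15 lists did not pass camera between vitrified and fresh oocytes. Cytosolic ribosomal protein genes had a median of -0.26 (camera adjusted p = 0.0628; 1 lower over all genes, 2 lower adjusted over the list alone). Genes of DNA methylation and histone modification had a median of -0.18 (0.0648; 1 lower adjusted over the list alone). Camera adjusted p-values were 0.0762 for blood and immune cell markers, 0.149 for autophagy and the proteasome and 0.165 for maternal mRNA storage and decay. They were 0.335 for the spindle and cytoskeleton, 0.335 for osmotic transport, 0.491 for DNA repair and 0.663 for apoptosis regulators. The remaining values were 0.936 for heat shock proteins, 0.936 for the unfolded protein response, 0.936 for calcium handling and egg activation, 0.936 for lipid metabolism, 0.936 for immediate early genes and 0.952 for cumulus and granulosa cell markers. In these 13 lists edgeR called 0 genes over all genes tested. Adjusted over the list alone it called 2 lower genes of osmotic transport, 2 higher genes of lipid metabolism and at most 1 in any other list. Of all 21 lists 6 passed camera, 0 with an estimated correlation and 3 without fresh library 1.

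**Figure D3:**
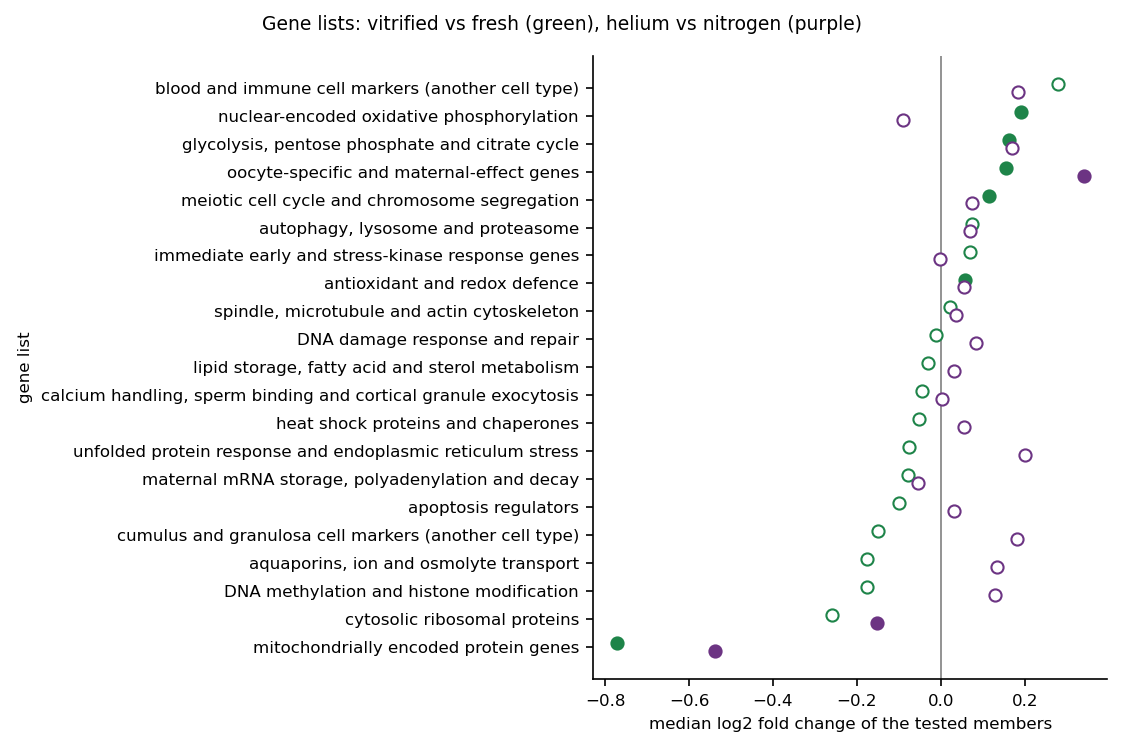
Median log2 fold change of the tested members of each of the 21 gene lists, for vitrified against fresh (green) and helium against nitrogen (purple), filled where the camera adjusted p was under 0.05. Mitochondrially encoded genes had the lowest medians, -0.77 and -0.54.

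Each helium group was compared with fresh oocytes to ask what cooling in liquid helium changed at each concentration. With helium at 5.6 M, SNRPC rose from 79.5 ± 18.8 to 309 ± 60.1 CPM (SD, n = 3 each). PYM1, a factor that takes apart exon junction complexes, rose from 7.13 ± 0.432 to 20.6 ± 3.96 CPM, the centrosomal kinase gene NEK2 from 53.1 ± 10.2 to 106 ± 10.3 and the spindle gene NUSAP1 from 955 ± 116 to 1810 ± 305. NPC2, a cholesterol carrier of the lysosome, fell from 20.3 ± 3.67 to 8.42 ± 0.433 CPM and the splicing regulator gene HNRNPL from 115 ± 8.38 to 56.3 ± 8.86. With helium at 6.6 M, PRDX2 rose from 208 ± 35.1 to 508 ± 26.3 CPM. AIMP2, a scaffold of the aminoacyl-tRNA synthetase complex, rose from 14.5 ± 3.89 to 35.1 ± 9.99 and the complex I gene NDUFS3 from 12.3 ± 3.45 to 29.4 ± 8.05. The ubiquitin ligase gene RNF145 fell from 90.4 ± 22.6 to 42.8 ± 5.52 CPM and CPEB3, a gene of a regulator of mRNA translation, from 126 ± 3.95 to 70.9 ± 13.6. In each of these genes all 3 helium libraries lay beyond all 3 fresh ones. The naming rule required this separation, which chance gives 10% of the time for a single gene, so it adds no support.

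With helium at 5.6 M, 40 genes passed edgeR's test against fresh, 16 higher and 24 lower. By edgeR the log2 fold change was 1.95 for SNRPC (SE 0.21, adjusted p = 0.000104), 1.53 for PYM1 (SE 0.33, adjusted p = 0.0461) and 0.99 for NEK2 (SE 0.21, adjusted p = 0.0402). It was -1.03 for HNRNPL (SE 0.21, edgeR adjusted p = 0.0402). With helium at 6.6 M, 53 genes passed by edgeR, 31 higher and 22 lower. Among them were SNRPC at 1.75 (SE 0.21, adjusted p = 0.000556), PRDX2 at 1.29 (SE 0.18, edgeR adjusted p = 0.00202) and CPEB3 at -0.83 (SE 0.18, adjusted p = 0.0383). With the replicate number as a block 3 genes passed at 6.6 M (1108 at an unadjusted p under 0.05). The 53 kept a median of 1 of their log2 fold change (quartiles 0.993 to 1.01). Both groups hold the same replicate numbers, so the block leaves their mean difference nearly unchanged and this share adds no support. Under the block SNRPC (edgeR adjusted p = 0.00336) and PRDX2 (0.0234) passed, and RNF145 and SERPINE2 (0.0905 each), NDUFS3 (0.112), CPEB3 (0.135) and AIMP2 (0.14) did not. SERPINE2, a protease inhibitor gene that granulosa cells also express, rose by 1.5 on the log2 scale at 6.6 M (SE 0.32, edgeR adjusted p = 0.0317), from 13.6 ± 4.88 to 38.3 ± 15.1 CPM. Some markers of cumulus and granulosa cells were highest in helium 6.6 M library 2, with 130 CPM (not scaled) of TIMP1, 30.8 of TNFAIP6, 61.8 of SERPINE2 and 16.8 of VIM. Their group means in fresh oocytes were 0.416, 0.844, 14.1 and 1.17. At 5.6 M camera called higher oocyte-specific genes (adjusted p = 0.000601) and meiotic genes (0.0283), and lower mitochondrially encoded genes (3.48e-08) and ribosomal protein genes (0.000601). None of these 4 lists held with an estimated correlation (adjusted p = 0.467, 0.267, 0.351 and 0.55). At 6.6 M the higher lists by camera were oocyte-specific genes (adjusted p = 0.000675), carbohydrate metabolism (0.00102), nuclear oxidative phosphorylation (0.00305) and antioxidant genes (0.032), and mitochondrially encoded genes were lower (2.72e-08). None of these 5 held either (adjusted p = 0.325, 0.256, 0.325, 0.256 and 0.263 with an estimated correlation). Helium 6.6 M library 2 held 4658 CPM (not scaled) summed over the oxidative phosphorylation list, against 3523 and 3912 in the other libraries of its group. At 5.6 M the count was 1, 2 and 1 without helium libraries 3, 4 and 5 in turn, and 2, 431 and 20 without fresh libraries 1, 2 and 3. At 6.6 M it was 5, 3 and 4 without helium libraries 1, 2 and 3, and 3, 598 and 29 without fresh libraries 1, 2 and 3. With depth class as a term, which rests on nitrogen 6.6 M library 3, 0 genes passed at either concentration. The signs of 40 of 40 and 53 of 53 genes were kept, which adds little support for genes called in these same libraries.

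Nitrogen groups were compared with fresh oocytes to ask the same of the conventional coolant. SNRPC rose to 322 ± 50.2 CPM with nitrogen at 5.6 M and to 330 ± 35.4 at 6.6 M, from 79.5 ± 18.8 in fresh oocytes (SD, n = 3 each). At 6.6 M transcripts of the translocation channel subunit SEC61G rose from 207 ± 46.2 to 521 ± 156 CPM. Those of the amino acid transporter SLC7A3 rose from 309 ± 70.0 to 709 ± 68.8 and those of the spliceosome protein CWC15 from 257 ± 36.1 to 547 ± 80.0. All 3 nitrogen libraries lay above all 3 fresh ones in each case, a separation that the naming rule required of every gene named here. By edgeR, SNRPC was the 1 gene past the threshold at 5.6 M (log2 fold change 2.01, SE 0.21, adjusted p = 7.33e-05). At 6.6 M 4 genes passed by edgeR. They were SNRPC at 2.05 (SE 0.21, edgeR adjusted p = 5.32e-05), SEC61G at 1.34 (SE 0.23, adjusted p = 0.0354), SLC7A3 at 1.2 (SE 0.21, adjusted p = 0.0354) and CWC15 at 1.09 (SE 0.19, adjusted p = 0.0354). At 5.6 M CWC15 (1.04, edgeR adjusted p = 0.0923), SEC61G (1.24, 0.0923), SLC7A3 (1.05, 0.127), UBE2C (1.07, 0.167) and PRDX2 (0.82, 0.18) did not pass, with all 3 nitrogen libraries above the fresh ones. At 6.6 M PRDX2 (0.94, edgeR adjusted p = 0.0529), UBE2C (1.19, 0.0529), MRPL20 (1.02, 0.0709) and SHKBP1 (-1.52, 0.0709) did not pass, with all 3 libraries on 1 side. Nuclear oxidative phosphorylation genes were higher as a list at both concentrations, with medians of 0.24 and 0.27 (camera adjusted p = 3.17e-05 and 1.57e-05, adjusted p = 0.326 and 0.348 with an estimated correlation). Genes of DNA methylation and histone modification were lower, with medians of -0.24 and -0.19 (0.019 and 0.0189, adjusted p = 0.399 and 0.416 with an estimated correlation). Camera also called higher antioxidant genes at 5.6 M (adjusted p = 0.0307, 0.312 with an estimated correlation). At 6.6 M it also called higher meiotic genes (camera adjusted p = 0.0223, adjusted p = 0.227 with an estimated correlation) and lower mitochondrially encoded genes (9.27e-06, adjusted p = 0.416 with an estimated correlation). Without fresh library 3 the count was 3 at 5.6 M and 23 at 6.6 M, and at 6.6 M it was 2 without fresh library 2 and 1 without nitrogen library 3. Without fresh library 1 it stayed at 4, but SNRPC was the 1 gene shared with the 4 above.

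Because all 4 vitrified groups were set against the same 3 fresh libraries, their fold changes were compared with simulated unchanged groups that share 3 simulated controls. For the helium groups 8 higher and 13 lower genes were shared, where independent lists would share 0.0588 and 0.0626. Lists that use the same fresh libraries are not independent, so these expected numbers are too low. At most 0 were shared in 20 simulations, but no gene was changed there and hardly any call could arise, so that count decides nothing. Fold changes of the helium groups correlated across genes at r = 0.816 (0.595 simulated), with a covariance of 0.182 against 0.0701 simulated. For the nitrogen groups r was 0.68 (0.525 simulated), with a covariance of 0.123 against 0.0691, and SNRPC was the 1 shared call (0.000474 for independent lists). At 5.6 M helium and nitrogen gave r = 0.521 (0.55 simulated) and a covariance of 0.103 against 0.0705, with 1 shared higher gene (0.0019 for independent lists). At 6.6 M they gave r = 0.587 (0.577 simulated) and a covariance of 0.119 against 0.0697, with 3 shared higher genes (0.0147 for independent lists). Genes are not independent replicates, and the 3 controls are too few to be split, so part of the excess may come from the shared controls. The simulations gave every group the same spread per gene. Yet fresh libraries differed by 14.4 to 30 in chi-square per degree of freedom and nitrogen 5.6 M ones by 5.52 to 12.7. Both helium groups also hold only deeper libraries, and a batch that goes with depth was not simulated here.

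Helium was then compared with nitrogen, 6 libraries against 6 over both concentrations, to ask what the coolant itself changed. Transcripts of NDUFA1, a complex I subunit, were lower with helium, at 35.3 ± 4.49 CPM against 84.2 ± 16.3 with nitrogen (SD, n = 6 each), and so were those of SON, a splicing cofactor of nuclear speckles, at 268 ± 25.5 against 515 ± 95.7. Transcripts of PLAUR, the urokinase receptor, were higher with helium, at 226 ± 41.5 against 150 ± 12.2 CPM, and so were those of the oxidoreductase WWOX, at 15.3 ± 2.33 against 8.61 ± 1.17. In these 4 genes all 6 helium libraries lay beyond all 6 nitrogen ones. NDUFA1 spans 4068880 to 4072037 on chromosome X and PLAUR 52202332 to 52215619 on chromosome 18 of UMD3.1.

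By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 56 genes passed between the coolants, 6 higher and 50 lower with helium. The log2 fold change was -1.26 for NDUFA1 (SE 0.17, edgeR adjusted p = 0.00135) and -0.95 for SON (SE 0.18, adjusted p = 0.0143). By edgeR it was 0.58 for PLAUR (SE 0.11, adjusted p = 0.0195) and 0.81 for WWOX (SE 0.18, adjusted p = 0.0314). GPR12, a receptor related to those that hold oocytes in meiotic arrest, rose by 1.11 (SE 0.25, edgeR adjusted p = 0.0425). MIF4GD rose by 0.87 (SE 0.20, edgeR adjusted p = 0.0425), and both genes were higher in 6 of 6 helium libraries. The transcription factor gene PAX9 rose by 1.29 (SE 0.28, edgeR adjusted p = 0.0296), with 3 of 6 helium libraries above all nitrogen ones. Other genes that fell with helium, by edgeR and in 6 of 6 libraries, were LYRM7, an assembly factor of complex III (-1.14, SE 0.20), and the histone deacetylase complex gene SAP30L (-1.01, SE 0.17). So were the calcineurin gene PPP3CA (-0.96, SE 0.21), the mitochondrial chaperone gene DNAJC19 (-1.17, SE 0.23) and DNAJC24 (-1.35, SE 0.26), and edgeR adjusted p ran from 0.00955 to 0.0296 over these genes. ND3 (-1.27), the ribosomal protein gene RPL37 (-1.15), the small nuclear RNA 7SK (-1.43) and Metazoa_SRP (-1.95) fell too, but have near-identical copies and are uncertain. In nitrogen 6.6 M library 3, the deeper nitrogen library, ND3 stood at 100 CPM, nearer to the helium than to the nitrogen mean, whereas NDUFA1 stood at 90.8 and SON at 568. Without single libraries the count was 30, 15 and 32 (helium 5.6 M libraries 3, 4 and 5), 24 and 28 (helium 6.6 M libraries 1 and 3) and 37 and 34 (nitrogen 5.6 M libraries 2 and 3). With depth class as a term, which rests on that library, 13 genes passed, 3 of them among the 56. The 56 kept a median of 1.08 of their log2 fold change (quartiles 0.781 to 1.35) and 56 of 56 their sign. They were called in these same libraries, so the kept shares and signs add little support.

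**Figure D4:**
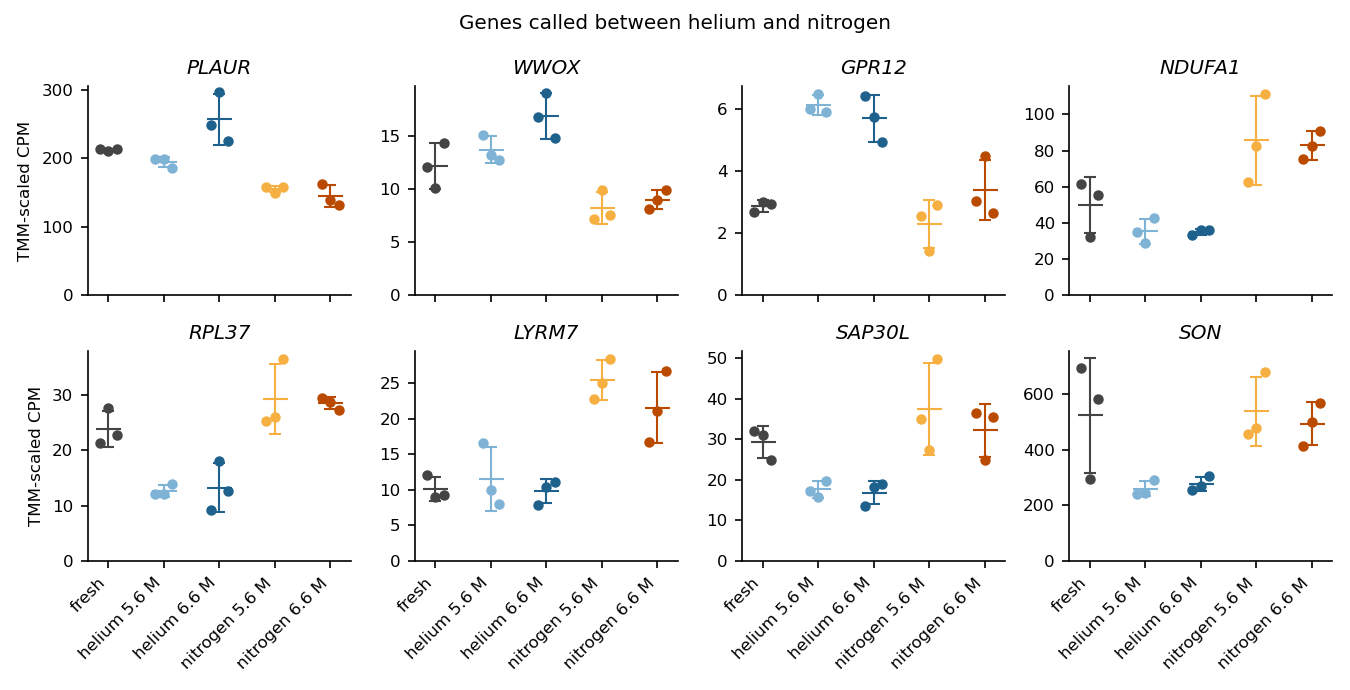
CPM (scaled by the trimmed mean of M-values) of 8 genes that passed between helium and nitrogen, in every library by group, with points for libraries, horizontal lines for means and bars for 1 SD (n = 3). PLAUR, WWOX and GPR12 lay higher with helium, and NDUFA1, RPL37, LYRM7, SAP30L and SON lower.

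In the lists for helium vs nitrogen, oocyte-specific and maternal-effect genes were higher with helium, with 23 of 28 above 0 at a median log2 fold change of 0.34 (camera adjusted p = 0.000463, adjusted p = 0.671 with an estimated correlation). Of these 28 genes edgeR called 0 over all genes and 0 adjusted over the list alone. WEE2, a kinase that helps to hold oocytes in meiotic arrest, stood at 0.52 (edgeR adjusted p = 0.104). Mitochondrially encoded genes were lower with helium, with 12 of 12 below 0 at a median of -0.54 (camera adjusted p = 2.94e-05, adjusted p = 0.671 with an estimated correlation). ND3 fell over all genes, and 4 fell adjusted over the list alone. The direction of this list was upward with depth class as a term (camera adjusted p = 0.223) and among the deeper libraries alone (camera adjusted p = 0.0201). Both fits rest on nitrogen 6.6 M library 3, the 1 deep nitrogen library and the one with the lowest mitochondrial share, so they do not decide the direction. Cytosolic ribosomal protein genes were lower at a median of -0.15 (camera adjusted p = 0.035, adjusted p = 0.675 with an estimated correlation), with RPL37 falling over all genes and 6 adjusted over the list alone. Nuclear oxidative phosphorylation genes did not pass as a list (camera adjusted p = 0.123). However, NDUFA1 fell over all genes, and 7 genes fell and 1 rose adjusted over the list alone. Of cumulus and granulosa markers 4 rose adjusted over the list alone and 0 over all genes by edgeR, and the list did not pass (camera adjusted p = 0.404). The number of lists past camera was 3, and 5 without nitrogen 5.6 M library 1.

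Within each concentration the coolants were compared 3 against 3. At 5.6 M edgeR called 0 genes, with 803 at an unadjusted p under 0.05 where 422 are expected by chance, while DESeq2 called 48 and limma 4. At 6.6 M edgeR called 0 genes, with 678 at an unadjusted p under 0.05, while DESeq2 called 8 and limma 0, and without nitrogen 6.6 M library 3 edgeR called 1. Oocyte-specific genes were higher with helium at 5.6 M (median 0.36, camera adjusted p = 0.0012, adjusted p = 0.632 with an estimated correlation) and at 6.6 M (median 0.33, camera adjusted p = 0.0148, adjusted p = 0.79 with an estimated correlation). At 5.6 M mitochondrially encoded genes (camera adjusted p = 3.49e-07), ribosomal protein genes (0.00132) and nuclear oxidative phosphorylation genes (0.022) were lower, with adjusted p = 0.632, 0.694 and 0.642 with an estimated correlation. At 6.6 M carbohydrate metabolism genes were higher (camera adjusted p = 0.0148, adjusted p = 0.79 with an estimated correlation).

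High and low cryoprotectant concentration were compared over both coolants, 6 libraries against 6, to ask what the extra cryoprotectant changed. FAM193A stood at 34.9 ± 2.07 CPM at 5.6 M and 57.3 ± 10.8 at 6.6 M in helium, and at 24.6 ± 8.94 and 42.2 ± 6.64 in nitrogen (SD, n = 3 each). Its log2 difference of 0.75 (SE 0.21) did not pass (edgeR adjusted p = 1). CD164, a sialomucin gene, stood at 83.6 ± 1.03 and 104 ± 6.28 CPM in helium and 64.0 ± 7.70 and 93.7 ± 11.9 in nitrogen. The autophagy protease gene ATG4C stood at 10.7 ± 1.35 and 12.9 ± 2.52 in helium and 7.31 ± 2.81 and 16 ± 2.81 in nitrogen. Neither passed (log2 differences 0.44 and 0.69, edgeR adjusted p = 1). ROBO1 stood at 34.1 ± 3.04 and 30.9 ± 1.93 CPM in helium and 44.4 ± 2.85 and 29.1 ± 2.86 in nitrogen (log2 difference -0.38, edgeR adjusted p = 1). Mitochondrially encoded genes were lower at the high concentration as a list, with 12 of 12 below 0 at a median of -0.24 (camera adjusted p = 0.00328, adjusted p = 0.824 with an estimated correlation). Over all genes edgeR called 0 of them, and adjusted over the list alone 0. By edgeR 0 of 8441 genes passed, with 189 at an unadjusted p under 0.05 where 422 are expected by chance, while DESeq2 called 0 and limma 1. In helium alone edgeR called 0 genes (169 at an unadjusted p under 0.05), DESeq2 0 and limma 0. In nitrogen alone edgeR called 0 (166 at an unadjusted p under 0.05), DESeq2 0 and limma 3. All 3 numbers lay under the 422 expected, so edgeR's test may be too cautious here. The 0 calls therefore do not show that the concentration had no effect. As lists, genes of ribosomal proteins (camera adjusted p = 0.00361), nuclear oxidative phosphorylation (0.00803) and carbohydrate metabolism (0.0213) were higher at the high concentration in helium, each with adjusted p = 0.61 with an estimated correlation. Helium 6.6 M library 2 stood apart in ribosomal genes, with a summed 4385 CPM (not scaled) against 3311 and 2954 in its group and 3091 to 3172 at 5.6 M. It did so in oxidative phosphorylation genes too, with 4658 against 3523 and 3912, and 3605 to 3932 at 5.6 M. In nitrogen mitochondrially encoded genes were lower (camera adjusted p = 2.66e-06, adjusted p = 0.772 with an estimated correlation). Library 3 stood apart there, with a summed 16750 CPM (not scaled) against 34410 and 34980 in the other 6.6 M libraries and 38790, 50020 and 30400 at 5.6 M. The number of lists was 1, and it was 3, 0 and 2 without helium 6.6 M libraries 1, 2 and 3. It was 0 without nitrogen 5.6 M library 2, and 3 and 0 without nitrogen 6.6 M libraries 2 and 3.

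A coolant by concentration interaction was tested to ask whether the concentration mattered differently in helium and in nitrogen. FIGLA, a transcription factor gene of the oocyte, stood at 7.61 ± 1.28 and 18.5 ± 6.58 CPM at the low and high concentrations in helium. In nitrogen it stood at 14.2 ± 3.71 and 10.6 ± 3.58 (SD, n = 3 each). Its interaction of 1.68 on the log2 scale (SE 0.46) did not pass over all genes (edgeR adjusted p = 1), and FIGLA was the 1 call among the oocyte-specific genes adjusted over the list alone. By edgeR 0 of 8441 genes passed, with 177 at an unadjusted p under 0.05 where 422 are expected by chance, while DESeq2 called 0 and limma 1. The test may be too cautious here too, so the 0 calls do not show that there was no interaction. As lists, mitochondrially encoded genes had a positive interaction (helium minus nitrogen, median 0.42, camera adjusted p = 0.0152), as had ribosomal protein genes (0.16, 0.0287) and immediate early genes (0.28, 0.0453), each with adjusted p = 0.627 with an estimated correlation. Single libraries stood apart in these lists: nitrogen 6.6 M library 3 held 16750 CPM (not scaled, summed) of mitochondrially encoded genes against 34410 and 34980 in its group. Helium 6.6 M library 2 held 4385 of ribosomal protein genes against 3311 and 2954, and 1426 of immediate early genes against 1159 and 1066.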

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

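The tests of counting depth, gene length and a library batch were chosen after the results were seen, whereas the counts of regroupings of the libraries were planned. Between helium and nitrogen the change from fresh differed for 56 genes by edgeR, among them NDUFA1 and SON, which were lower with helium. Of the gene lists, 3 differed between the coolants by camera: oocyte-specific genes higher, and mitochondrially encoded and ribosomal protein genes lower with helium. Between the concentrations 1 list differed, the mitochondrially encoded genes, and 3 lists had a coolant by concentration interaction, the mitochondrially encoded, ribosomal protein and immediate early genes. None of these 7 list results held with an estimated correlation. For helium against nitrogen 44 of 100 regroupings gave 3 lists or more (highest other 6), and for the concentrations 86 of 100 gave 1 list or more (highest other 6), so chance cannot be excluded for these lists.

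The 56 genes that differed between helium and nitrogen were more than in any other of 100 regroupings (highest other 2), so a chance division of these libraries was excluded for their number. The regroupings took libraries as independent, though replicates may be technical, and they mixed depth with the coolants. They therefore say that these sets of libraries differed in the 56 genes and not why. Unequal total counts alone did not account for them, since with each library thinned to the smallest total 37 of 56 still passed and 10 draws gave 32 to 46 calls; the median share of the log2 fold change kept, 1 (quartiles 0.938 to 1.05), adds little because thinning leaves fold changes near their values, and helium libraries still held 11284 to 11996 genes above 0 against 10702 to 11054 in nitrogen ones. A smooth trend with gene length over all genes did not account for them as the whole cause, since they kept 0.928 without it (0.795 to 1.08) and 39 of 56 still passed. That trend was weak (Spearman correlation 0.0564), so its removal could change little. The called genes were short, with median lengths of 1113 bases for the higher and 624 for the lower ones, against 2041 for tested genes. A difference that touches short transcripts therefore stays open. A library batch that went with depth stays open: nitrogen 6.6 M library 3, the 1 deep nitrogen library, lay at a median of 0.284 between the other nitrogen libraries (0) and the helium libraries (1) in genes called without it (quartiles -0.0149 to 0.511), while the other nitrogen libraries lay at -0.223 to 0.361 and the helium libraries at 0.853 to 0.999. A single library cannot decide this, so batch and coolant cannot be told apart: the coolant stays open for NDUFA1 and SON, which were as high in that library as in the other nitrogen ones, and a batch may account for part of the lower ND3, which was low in it.

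The lower share of mitochondrial transcripts with helium was the other pattern in which nitrogen 6.6 M library 3 stood apart. Its share was 2.41%, below all other nitrogen libraries (4.06 to 6.29%) and below the lowest helium library (2.79%). If the coolant alone set the share, this library was predicted to lie above the helium range, and it did not. A batch that goes with depth was predicted to put it below the other nitrogen libraries and not above the helium range, and it lay there. Both predictions were written after the data had been seen. The first decides nothing, since a shallower library, nitrogen 5.6 M library 3 (4.06%), also lay below the highest helium library (4.21%). Helium and nitrogen shares did not differ past the threshold either (exact permutation test, two-sided, p = 0.149). Because 1 library is too few and fresh libraries ranged from 4.14 to 8.66%, the coolant and a batch cannot be told apart.

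The 43 genes that differed between vitrified and fresh oocytes were more than in any other of 100 regroupings (highest other 34). The regrouping with 34 joined fresh library 2 with helium 6.6 M libraries 1 and 2. The regroupings also mixed the coolants, and depth with them, so they asked whether any groups differed and not about vitrification alone. Chance was therefore not excluded for the number of genes between vitrified and fresh, which fell to 5 without fresh library 1. Unequal total counts alone did not account for the 43 genes. With each library thinned to the smallest total, 34 of 41 with a value still passed and 10 draws gave 35 to 50 calls. The median share of the log2 fold change kept, 1.01 (quartiles 0.986 to 1.03), adds little for the reason above, and helium libraries still held 11284 to 11996 genes above 0 against 10351 to 11409 in fresh ones. Among the 8 shallower libraries they kept 0.923 (quartiles 0.784 to 1.02). The higher genes kept 0.952 (0.922 to 1.03) and the lower genes 0.778 (0.461 to 0.875). These libraries include the fresh ones that gave the calls. Simulated data with a batch alone, in which the fresh libraries were drawn anew as well, kept a median of 0.617 over both directions (highest 0.832, with 0 to 17 genes called per simulation). The kept shares therefore decide little, and 1 gene passed among the shallower libraries. A batch that goes with depth cannot be told apart from vitrification.

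The remaining counts were set against regroupings of the same libraries. Lists between vitrified and fresh numbered 6, and 2 of 100 regroupings, the real one included, gave as many (highest other 7). Since another regrouping gave more lists and the regroupings also mixed the coolants, chance was not excluded for their number. With an estimated correlation 0 of the 6 lists passed. For the concentrations and the interaction 0 genes passed, a count that any regrouping reaches (100 of 100 each, highest other 3 and 48), so the regroupings decide nothing there. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real count was 40 with 1 as the highest other for helium 5.6 M against fresh, 53 with 0 for helium 6.6 M (the splits that part every same-number pair included), 1 with 0 for nitrogen 5.6 M and 4 with 393 for nitrogen 6.6 M. That count of 393, with fresh libraries 1 and 2 and nitrogen 6.6 M library 1 on 1 side, points to a structure of the samples. For helium against nitrogen the real count was 0 at 5.6 M with 0 as the highest other and 0 at 6.6 M with 1, and for the concentrations 0 in helium with 1 and 0 in nitrogen with 2.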

How the results depend on the processing

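Limma with a pseudocount of 1, equal totals, the gene length trend, depth class, the depth subsets and the block joined with another choice were added after the data had been seen, and the other alternatives were planned. SNRPC passed between vitrified and fresh in 27 of 27 alternatives, with log2 fold changes of 1.79 to 2.15, SLC7A3, UBE2C, PRDX2, CWC15 and ND3 in 23 of 27, and NDUFA1 between the coolants in 23 of 25. The genes followed through the alternatives were those named by the rule and the members with the smallest p of lists that passed; they kept their direction in each alternative run for them, except 4 genes between helium and nitrogen. With depth class as a term and among the deeper libraries alone, fits that both rest on nitrogen 6.6 M library 3 as the 1 deep nitrogen library, these turned positive: ATP8 at 0.22 and 0.35, ND6 at 0.57 and 0.51, ND2 at 0.26 and 0.28, and RPS13 at 0.13 and 0.065. Counts below are in the order helium 5.6 M, helium 6.6 M, nitrogen 5.6 M and nitrogen 6.6 M against fresh, then all vitrified against fresh, then helium against nitrogen; main counts were 40, 53, 1, 4, 43 and 56.

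Without a count filter, which tests more genes, they were 160, 239, 26, 60, 142 and 344. With a mean of at least 5 FPKM the counts against fresh were 63, 80, 4 and 12. DESeq2 gave 268, 319, 37, 80, 216 and 268. Limma with a pseudocount of 1 gave 20 and 21 for nitrogen and 82 for all vitrified; with 0.1 it gave 12, 9 and 108, and 28 for helium against nitrogen. Quantile normalization gave 80, 129, 17, 17 and 132. With only the libraries compared in the fit the counts were 5 and 2 for helium against fresh, 1 for nitrogen 6.6 M and 308 between the coolants. Counts thinned to equal totals gave 24 and 27 for helium and 7 for nitrogen 6.6 M. Depth class as a term gave 0, 0, 2, 1, 1 and 13, and without the length trend helium 6.6 M gave 28. Among shallower libraries 1 gene passed for nitrogen 6.6 M and 1 for all vitrified, and among deeper libraries 274 passed between the coolants, where the nitrogen arm is 1 library that is assumed to vary like the other groups, so this count tests little; fewer libraries enter these fits. Apart from the number of genes or libraries, the cause was not tested.

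Comparisons with 0 genes gained some. For the concentrations no filter gave 3 and each limma fit 1; for the interaction no filter gave 2 and each limma fit 1. Helium against nitrogen at 5.6 M gave 61 without a filter, 1 with a mean of 5 FPKM, 48 with DESeq2, 4, 4 and 7 with limma at pseudocounts of 1 and 0.1 and on quantile-normalized values, 31 with only those libraries, 2 at equal totals and 2 with depth class. At 6.6 M it gave 67 without a filter, 8 with DESeq2, 5 with quantile normalization, 3 with depth class and 53 among deeper libraries. Concentrations in helium gave 15 without a filter, and in nitrogen 3 without a filter and 3, 1 and 3 with the limma fits. With an estimated correlation 0 lists passed for all vitrified, 0 for the coolants and 0 for the concentrations. Between the coolants 5 lists passed without a filter and 5 among deeper libraries, and for the concentrations 0 with depth class. The difference in detected genes was -22.4 at 5 FPKM. The cause was not tested.

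Leaving out each library gave 1 to 431 genes for helium 5.6 M, 3 to 598 for helium 6.6 M, 1 to 3 for nitrogen 5.6 M, 1 to 23 for nitrogen 6.6 M, 5 to 243 for all vitrified and 15 to 71 between the coolants. The extremes came without fresh library 1 or 2 for all vitrified, of which the 5 shared 2 genes and the 243 shared 36 with the 43 (without fresh library 3, 39 passed and 23 were shared), and without helium 5.6 M library 4 or nitrogen 6.6 M library 1 between the coolants. It gave 0 to 1 between the coolants at 6.6 M, and 0 to 0 at 5.6 M, for the concentrations, in helium, in nitrogen and for the interaction. Lists numbered 3 to 8, 2 to 5 and 0 to 3. The difference in detected genes was -106 to 554 and that in mitochondrial share -2.77 to -0.513.

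With the replicate number as a block, counts were 3 for helium 6.6 M, 1 for nitrogen 5.6 M, 1 for nitrogen 6.6 M, 1 for all vitrified and 0 between the coolants, and 2 lists for the concentrations. Same-number pairs correlated at a median of 0.053 (-0.355 to 0.431), 10 of 22 above 0.1, and 4 of 12 libraries matched their own number best. In helium 6.6 M and fresh alone all 3 pairs lay over 0.1 (0.147 to 0.306), so those numbers were taken as pairs, a hint from the data and not the design; elsewhere the libraries share only a number. For helium 6.6 M the block gave 17 genes on these 6 libraries alone, 2 without the length trend, 4 at equal totals and 0 with depth class (251 at an unadjusted p under 0.05), and the block by itself changed no list call of that comparison. With the block and depth class, mitochondrially encoded genes turned upward (camera adjusted p = 0.976), oxidative phosphorylation and antioxidant genes did not pass (0.821 each) and ribosomal protein genes were lower (6.68e-07, 0.665 with an estimated correlation). With the block and without the length trend, oxidative phosphorylation (0.103) and antioxidant genes (0.126) did not pass, ribosomal protein genes were lower (0.0139, 0.615 with an estimated correlation) and blood and immune markers higher (0.0358, 0.376). Comparisons of helium 5.6 M with a single other group were left out of the block as planned, since the labels number its libraries 3, 4 and 5 and it shares only number 3; a blocked contrast would rest on that 1 pair. With each library thinned to the smallest total, 1601519 counts, the median of 10 draws was 24.5 and 33.5 genes for helium 5.6 M and 6.6 M, 3 and 8.5 for nitrogen, 43 for all vitrified and 38 between the coolants, so fewer genes passed for each helium group against fresh and between the coolants, and no fewer in the other comparisons named.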

Other observations

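All tests of gene families here were chosen after the data had been seen. Genes of the mitochondrial ribosome had positive medians after vitrification: the 42 MRPL genes of the large subunit had a median log2 fold change of 0.22 against fresh, with 34 above 0 (camera adjusted p = 0.000107, but adjusted p = 0.982 with an estimated correlation), and 1 of them, MRPL20, passed by edgeR. The MRPL median was 0.06 with depth class as a term, a fit that rests on nitrogen 6.6 M library 3, and 0.20 among the 8 shallower libraries. The 24 MRPS genes of the small subunit had a median of 0.21 with 20 above 0 (camera adjusted p = 0.0416, adjusted p = 0.982 with an estimated correlation), which was -0.01 with depth class as a term and 0.07 among the shallower libraries. NDUF genes, which encode the nuclear subunits and assembly factors of complex I, had a median of 0.21 with 27 of 34 above 0 (camera adjusted p = 0.000948, adjusted p = 0.982 with an estimated correlation), which was -0.01 with depth class as a term and 0.29 among the shallower libraries. RPS genes of the small cytosolic ribosomal subunit were lower, with a median of -0.33 and 5 of 26 above 0 (camera adjusted p = 0.0416, adjusted p = 0.996 with an estimated correlation), which was -0.67 with depth class as a term. Fold changes fell with gene length in this comparison (Spearman correlation -0.212 over 8441 genes), and without the length trend the medians were 0.07 for MRPL, 0.06 for MRPS, 0.09 for NDUF and -0.39 for RPS genes.

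Between helium and nitrogen, NDUF genes had a median of -0.14, with 11 of 34 above 0 and 3 lower by edgeR, and RPS genes a median of -0.18 with 6 of 26 above 0 (camera adjusted p = 0.0159 for each, adjusted p = 0.749 and 0.798 with an estimated correlation). The NDUF median ranged from -0.39 with depth class as a term to -0.07 with quantile normalization, and that of RPS genes from -0.57 with depth class as a term to -0.09 with counts thinned to equal totals. Of 74 families 4 passed camera between vitrified and fresh, 3 between the coolants and 0 between the concentrations, and 0 with an estimated correlation in any comparison.

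Some genes used as markers of cumulus and granulosa cells were found at similar levels in every group, as plain CPM: the hyaluronan synthase gene HAS2 at 96.2 to 120, the cholesterol transport gene STAR at 163 to 192 and the prostaglandin synthase gene PTGS2 at 62.6 to 79.7. Others were concentrated in helium 6.6 M library 2, with INHA at 4.49, CYP11A1 at 6.37 and KRT18 at 4.05 CPM. TIMP1 averaged 8.39 CPM with helium at 5.6 M and 45.4 at 6.6 M, where library 2 held 130 and libraries 1 and 3 held 0 and 6.68, against 0.416 in fresh oocytes, 0.436 with nitrogen at 5.6 M and 1.02 at 6.6 M. Without helium 6.6 M library 2, 38 genes passed between the coolants, 46 between vitrified and fresh and 3 between helium 6.6 M and fresh.

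On the first principal component, which held 26.9% of the variance, fresh library 2 lay at -36.7 and fresh libraries 1 and 3 at 34.5 and 29.5, while the vitrified libraries lay between -29.4 and 26.3.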
